A study of Rattus norvegicus with 22 samples.

How the data were processed

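RNA sequencing and ATAC sequencing (a map of open chromatin, read from where a transposase inserts adapters into nuclear DNA) were taken from the prefrontal cortex of male Sprague-Dawley rats. The labels give 4 treatments: control, WIN (a synthetic cannabinoid receptor agonist), cocaine, and WIN with cocaine. There were 3 RNA libraries and 1 ATAC library per treatment. A further 6 RNA libraries of the nucleus accumbens, 3 labelled cocaine and 3 labelled WIN with cocaine, were not analysed here. Groups and replicate numbers came from the sample titles. The labels do not say whether the replicates are separate animals, so the p-values measure the spread between these samples, which may be technical.

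The authors deposited 1 table of FPKM values (reads per gene scaled to the gene's length and the library's total) for the 12 prefrontal cortex RNA libraries. Per the labels' protocols, 1 µg of total RNA entered a stranded RNA library kit. Per the submitters' processing notes, HISAT2, HTSeq and DESeq were used, with no versions; the genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping antisense genes or close paralogs may be shared. The table listed 29663 genes, of which 26689 had Ensembl rat gene IDs and 2974 had IDs of another series. For the ATAC libraries the authors deposited regions with a whole-number score at each summit, in separate tracks per library, and 1 track of active regions that merges the 4 libraries. Per the labels' protocols, nuclei came from flash frozen tissue before tagmentation. Per the submitters' processing notes, BWA and MACS2 2.1.0 were used; whether insertion sites were shifted for the transposase, how the scores were scaled and which genome build the coordinates follow are not given in the sources used here. The scores are the authors' own and were used to describe and rank regions within a library.

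Within each gene the FPKM values of the 12 libraries were whole multiples of 1 step once each library was scaled by 1 factor, which gave back the reads behind the values. All genes with a value had a whole-read solution. As a check, the gene lengths implied by these reads were compared with whole base pairs: of the 11615 genes with more than 200 reads in a library, 99.98% lay within 0.03 bp of a whole length after 1 common factor, against 6.0% by chance. Recovered totals ran from 20852442 to 27677077 reads per library. A tested gene had a median of 481 reads per library, and 5% of the tested genes had fewer than 25.7 on average. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom over genes with at least 20 reads in a pair ran from 8.49 to 67.9.

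The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean for each of the 4 groups over all 12 libraries, a trended prior variance and Benjamini-Hochberg adjustment within each comparison. Genes needed an FPKM of 1 or more in at least 3 libraries, which left 15326, 1278 of them without an Ensembl ID. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The 6 comparisons were cocaine against control, WIN against control, WIN with cocaine against each of the other 3 groups, and the interaction of the treatments, which is the difference between the cocaine change with WIN and the cocaine change without it. A gene was called at an adjusted p under 0.05. The procedure was tested on simulated data with the gene means and residual spread of these libraries and 200 changed genes among 15326. For cocaine against control it recovered 45% of genes changed 1.5-fold and 78% of genes changed 2-fold, and for the interaction 14% and 50%. These simulated libraries vary independently from gene to gene, which real libraries do not. They also vary by the same spread in all 12 libraries, whereas library weights gave WIN replicate 3 a weight of 0.30, the lowest. The recovery in the real libraries may therefore differ.

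The tests, the filter, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 10 genes with the smallest p in each direction among called genes with a mean FPKM of at least 1, or 5 in each direction as values where none was called, passed over genes without a symbol, added a fixed set of genes by symbol, and took the 3 highest-scoring ATAC regions of each library that overlap no region of the others. The deposited table does not pair its IDs with gene names, and none of its IDs matched the reference table at hand (assembly GRCr8, 47357 genes, 0 with an Ensembl ID). The 42 gene lists fixed by symbol, the genes named by symbol and the share of promoters with an ATAC region were therefore not analysed here. In their place 2 IDs in each direction are followed through the 4 groups. They have the smallest p in cocaine against control among Ensembl IDs with a mean FPKM of at least 1 over the 12 libraries. This limit was set after the data were examined.

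Alternatives covered the pseudocount, the filter, rescaling, the variance prior, library weights, a replicate block, fits of only the compared groups, leaving out each replicate, and a threshold of 0.10. Added after the data were examined were limma voom on the recovered reads, with and without library quality weights, fits without each library of the groups not compared, and a score per library: the mean log2 value of the 500 genes with the smallest p among those higher in cocaine than control, minus that of the 500 lower. ATAC regions were compared with bedtools 2.31.1, with an overlap of at least 1 bp, and are given with 1-based positions. With 1 ATAC library per treatment no test was run on the ATAC regions, and intervals on shares are 95% Wilson intervals that cover counting error only.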

Results

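The series asks how exposure to a cannabinoid during adolescence alters the later response to cocaine in the rat brain. Prefrontal cortex was profiled by RNA sequencing in 12 libraries, 3 each for control, WIN, cocaine and WIN with cocaine, and by ATAC sequencing in 1 library for each treatment. The recovered depth of the RNA libraries was 20852442 to 25911627 reads for control, 24754334 to 27677077 for WIN, 23155951 to 26170665 for cocaine and 22106025 to 27101698 for WIN with cocaine. The number of genes at an FPKM of 1 or more was similar in all libraries, from 14589 to 14932. The 10 most abundant genes took 5.47% to 7.51% of the reads.

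The main axis of variation separated the cocaine from the control libraries. The first principal component of the log2 values held 28.5% of the variance and placed the 3 cocaine libraries at 9.96, 22.88 and 27.29, and the 3 control libraries at -20.21, -10.26 and -8.45. The 3 libraries of WIN with cocaine lay between them, at -5.56, -0.16 and 4.84. WIN replicates 1 and 2 lay with the controls, at -18.78 and -11.88, whereas WIN replicate 3 lay at 10.33, level with cocaine replicate 3.

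**Figure D1:**
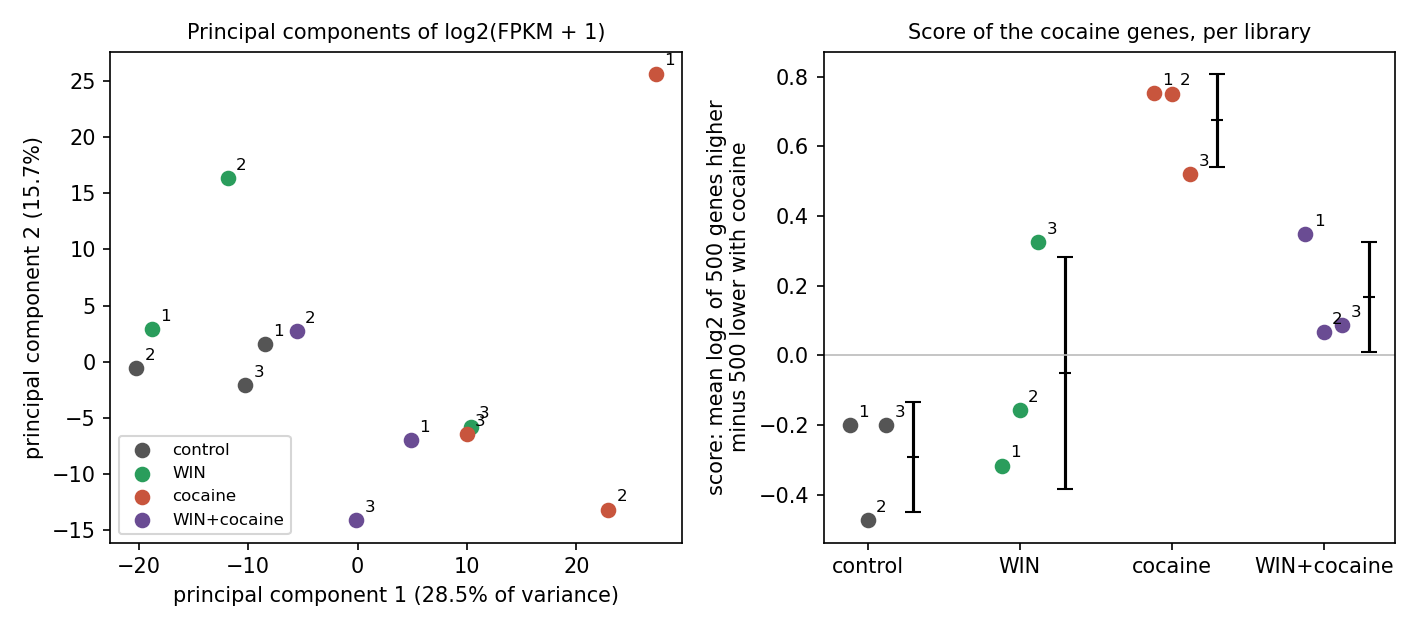
Left, the 12 RNA libraries on the first 2 principal components of log2(FPKM + 1), with replicate numbers beside the points and colours for the 4 groups. Right, the score of the cocaine genes per library (mean log2 value of 500 genes higher minus 500 genes lower in cocaine than control), with the group mean and SD as bars; the genes were chosen on the control and cocaine libraries, and WIN replicate 3 stands at 0.32, above the other WIN libraries.

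Cocaine against control, the comparison of the drug without earlier cannabinoid, held the broadest difference. Of 15326 genes, 4768 had an unadjusted p under 0.05 in limma, against 766 expected by chance, and they were evenly divided, with 2313 higher and 2455 lower in cocaine. The differences were small: 270 of these genes were at least 1.5-fold higher and 93 at least 1.5-fold lower on the log2(FPKM + 1) scale. In 6132 genes, or 40.0%, the 3 cocaine values did not overlap the 3 control values, where chance gives 10% for 3 against 3. Of the 1278 tested genes without an Ensembl ID, 228 had an unadjusted p under 0.05, 69 higher and 159 lower; their median log2 difference was -0.05, beside -0.02 for all genes, and this difference was not tested. Without control replicate 2 the count of all genes at that p was 2849, and genes without an Ensembl ID stood at 40 higher and 81 lower. Without cocaine replicate 2 the latter stood at 51 higher and 91 lower.

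No gene passed an adjusted p of 0.05 in limma, the smallest being 0.0596, and at 0.10 there were 3037 genes, 1544 higher and 1493 lower. Leaving out 1 of the compared libraries lowered the count at 0.10 to 0 without cocaine replicate 1, 0 without cocaine replicate 2, 1 without control replicate 2, 1 without control replicate 3 and 1664 without control replicate 1; it was 2946 without cocaine replicate 3. The count at 0.05 depended on WIN replicate 3, which enters the estimate of the spread: without that library the comparison called 2772 genes at 0.05, and without each of the other 5 WIN or WIN+cocaine libraries in turn it called 0. It called 2083 with library weights, 2276 with limma voom and quality weights, and 1378 with only the control and cocaine libraries, which leaves out all 6 of those libraries. Limma voom with equal weights called 0.

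The 2 Ensembl IDs with the smallest p in each direction, at a mean FPKM of at least 1, show the sizes involved. ENSRNOG00000023242 had an FPKM of 0.338 ± 0.0989 (SD, n = 3) in control and 3.50 ± 1.62 (SD, n = 3) in cocaine, a log2 difference of 1.69 with an SE of 0.24. At these low values the pseudocount set the size, and the log2 difference was 2.98 with a pseudocount of 0.1 and 3.20 with limma voom. ENSRNOG00000007387 had 20.3 ± 2.72 in control and 41.4 ± 3.86 in cocaine (SD, n = 3), a log2 difference of 1.00 with an SE of 0.16. ENSRNOG00000004950 was lower in cocaine, at 5.83 ± 0.258 against 9.84 ± 0.513 in control (SD, n = 3), a log2 difference of -0.67 with an SE of 0.09. ENSRNOG00000036813 was also lower, at 37.0 ± 3.10 against 57.3 ± 3.59 (SD, n = 3), a log2 difference of -0.62 with an SE of 0.10. Each had an adjusted p of 0.0596 in limma, and in each the 3 cocaine values lay beyond all 3 control values. The IDs were chosen for their p in this comparison, so this separation follows largely from the choice.

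**Figure D2:**
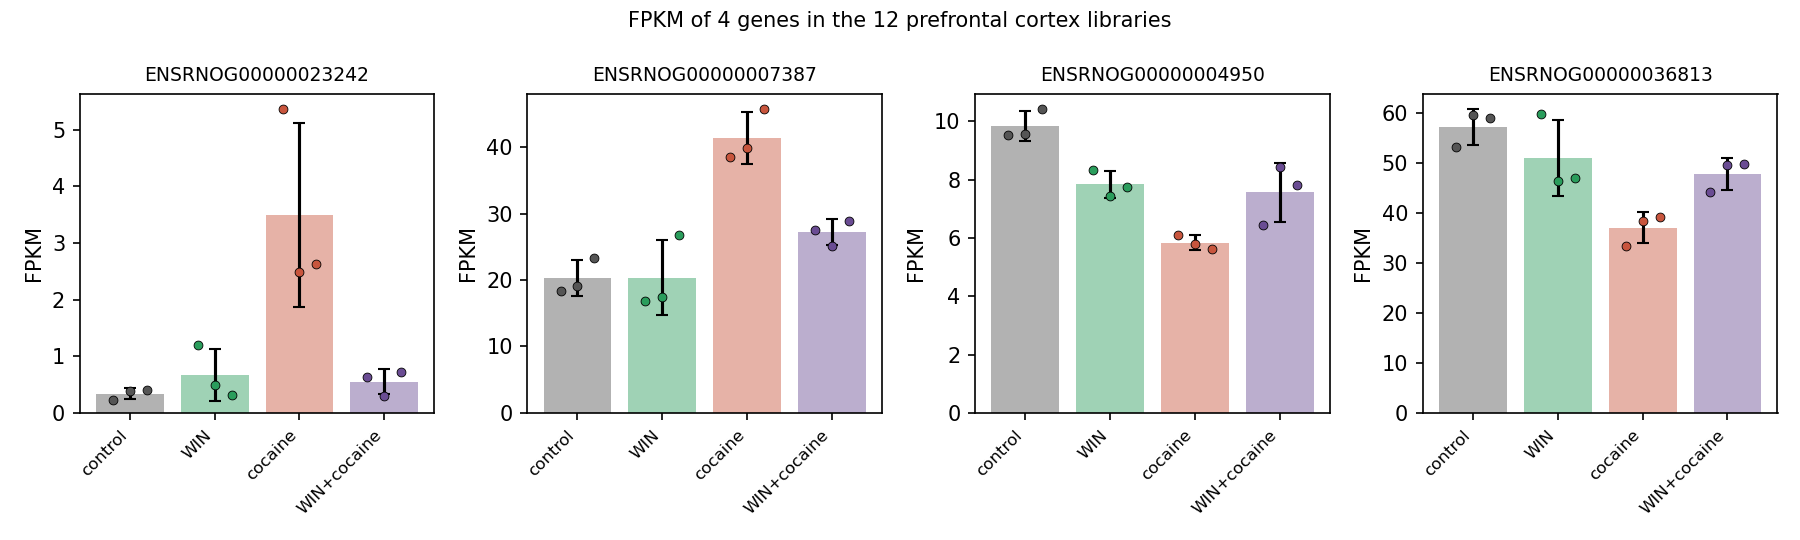
FPKM of the 4 IDs in the 4 groups, with bars for the group mean, error bars for the SD and points for the 3 replicates. ENSRNOG00000023242 averages 3.50 in cocaine and 0.550 in WIN with cocaine.

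WIN against control, the comparison of cannabinoid exposure alone, showed little difference. Limma called 0 genes, with a smallest adjusted p of 0.642, and limma voom called 0. At an unadjusted p under 0.05 there were 238 genes, fewer than the 766 expected by chance, 112 of them higher and 126 lower in WIN. The 4 IDs differed by log2 values of 0.29 (ENSRNOG00000023242), -0.02 (ENSRNOG00000007387), -0.30 (ENSRNOG00000004950) and -0.17 (ENSRNOG00000036813). That count was 478 without WIN replicate 1, 409 without WIN replicate 3, 148 without control replicate 2 and 889 with library weights.

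WIN with cocaine against cocaine asks whether earlier cannabinoid changes the state after cocaine. In value, the 4 IDs lay between cocaine and control. ENSRNOG00000023242 had an FPKM of 0.550 ± 0.221 (SD, n = 3) in WIN with cocaine, a log2 difference from cocaine of -1.49 with an SE of 0.24 and an unadjusted limma p of 5.61e-05. ENSRNOG00000007387 had 27.2 ± 1.93, ENSRNOG00000004950 had 7.57 ± 1.01 and ENSRNOG00000036813 had 47.9 ± 3.21 (SD, n = 3), with log2 differences of -0.59, 0.32 and 0.36. These IDs were chosen for their cocaine values, so part of this return follows from the choice. Over all genes limma called 0 and limma voom called 0; the smallest adjusted p in limma was 0.468, and 1623 genes had an unadjusted p under 0.05, of which 928 were higher and 695 lower in WIN with cocaine. That division turned with the scaling, with 700 higher and 876 lower after median ratio rescaling, and with single libraries, with 558 higher and 652 lower without cocaine replicate 2 and 503 higher and 545 lower without WIN+cocaine replicate 2. Among the 1623, genes without an Ensembl ID stood at 91 higher and 16 lower, and at 80 higher and 21 lower after median ratio rescaling. They stood at 63 higher and 32 lower without WIN+cocaine replicate 1, and at 53 higher and 12 lower without cocaine replicate 2. The opposite lean of such genes in cocaine against control rests on the same cocaine libraries. The count of 1623 genes was 1010 without cocaine replicate 1 and 1048 without WIN+cocaine replicate 2, but 2134 without cocaine replicate 3 and 2350 without WIN replicate 3.

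WIN with cocaine against WIN gives the cocaine response in animals that had received WIN. Limma called 0 genes and limma voom called 0, the smallest adjusted p in limma was 0.975, and 576 genes had an unadjusted p under 0.05, 392 higher and 184 lower. That division was more even in some alternatives, with 344 higher and 245 lower after quantile normalization. It was 213 and 176 without WIN+cocaine replicate 1, and 1254 and 1007 without WIN replicate 3. ENSRNOG00000007387 was higher in value, with a log2 difference of 0.43 and an SE of 0.16, and the other 3 IDs differed by -0.08, -0.05 and -0.08. Without WIN replicate 3 the count at an unadjusted p under 0.05 was 2261, so this comparison depends on that library; it was 359 without WIN replicate 2 and 946 without WIN+cocaine replicate 2.

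The genes that separated cocaine from control leaned the same way in this comparison, by less. Of the 500 genes higher in cocaine with the smallest p, 466 were higher in WIN with cocaine than in WIN, and of the 500 lower, 411 were lower. Together 87.7% of these genes had the same sign in both comparisons, beside 63.4% of all genes tested. Their median log2 differences were 0.15 and -0.07, beside 0.47 and -0.43 in cocaine against control, on which they were chosen. The score built from these genes was -0.05 ± 0.33 in WIN and 0.17 ± 0.16 in WIN with cocaine (SD, n = 3), a difference of 0.22 with an exact two-sided permutation p of 0.4; 3 libraries against 3 cannot give a p below 0.1. The difference was 0.48 without WIN replicate 3, 0.06 without WIN replicate 1 and 0.10 without WIN+cocaine replicate 1. The score was -0.29 ± 0.16 in control and 0.67 ± 0.13 in cocaine (SD, n = 3).

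WIN with cocaine against control compares both treatments with neither. Limma called 0 genes and limma voom called 0, with a smallest adjusted p of 0.617 in limma, and 1212 genes had an unadjusted p under 0.05, 836 higher and 376 lower. After quantile normalization the division was 697 higher and 505 lower. The count was 565 without control replicate 2 and 516 without WIN+cocaine replicate 1, but 1822 without WIN replicate 3 and 1868 with only the libraries compared. ENSRNOG00000007387 differed by a log2 value of 0.41 and ENSRNOG00000004950 by -0.35.

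**Figure D3:**
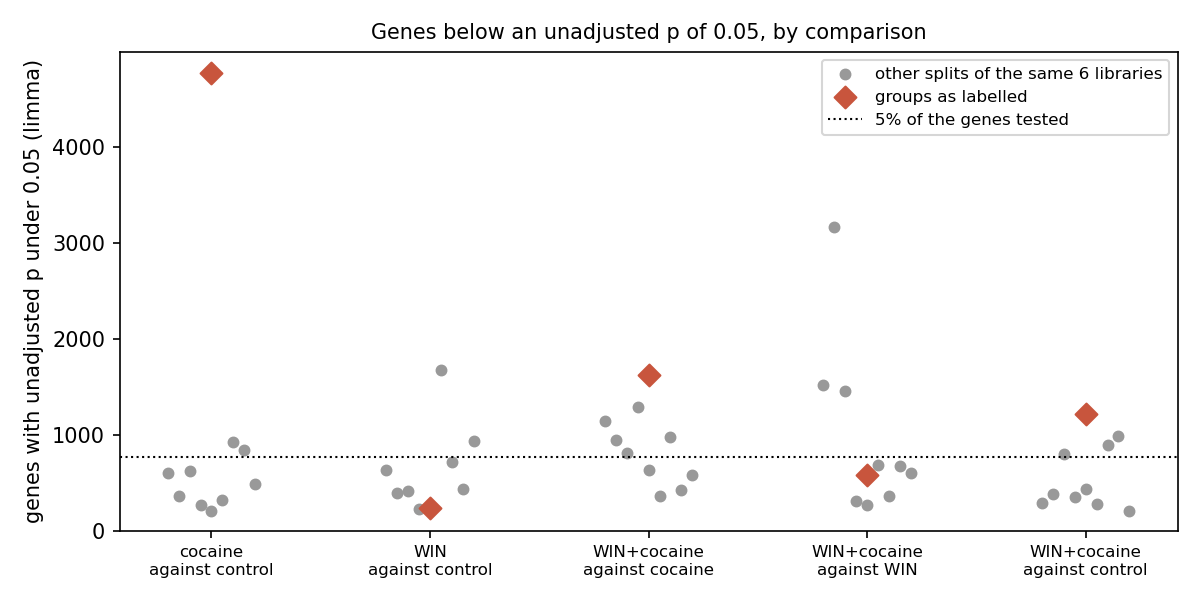
Genes with an unadjusted p under 0.05 in limma for 5 comparisons (vertical axis), for the groups as labelled (diamonds) and for the other 9 splits of the same 6 libraries (grey points); the dotted line marks 5% of the genes tested. Cocaine against control stands at 4768, and its highest other split at 921.

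The interaction tests whether the cocaine change differed with and without WIN. Limma called 0 genes and limma voom called 0, with a smallest adjusted p of 0.539 in limma, and 1382 genes had an unadjusted p under 0.05, 810 with a positive and 572 with a negative interaction. After median ratio rescaling these were 648 and 708, and without WIN+cocaine replicate 2 they were 487 and 542. The count was 596 without control replicate 2, 789 without WIN replicate 3, 857 without WIN+cocaine replicate 3 and 899 without cocaine replicate 1. It rose to 2062 without WIN replicate 1, 1891 without cocaine replicate 3 and 1786 without WIN+cocaine replicate 1. ENSRNOG00000023242 had an interaction of -1.78 with an SE of 0.34 and ENSRNOG00000004950 one of 0.62 with an SE of 0.13, each with an adjusted p of 0.539 in limma. These IDs were chosen on cocaine against control, which enters the interaction with the opposite sign, so part of these values follows from the choice. No gene thus passed the test of a difference between the cocaine changes.

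The changes were also compared across genes, which are not independent replicates. The cocaine changes without and with WIN, which share no library, correlated with Pearson's r of 0.227 and Spearman's rho of 0.338. The WIN changes without and with cocaine correlated with r of -0.223 and rho of -0.342. Both r lay inside the central 95% of 100 random regroupings of the 12 libraries, which ran from -0.329 to 0.335 and from -0.331 to 0.318. Without WIN replicate 3 the first r was 0.395 and the second 0.005, and without WIN replicate 1 they were 0.007 and -0.344.

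The ATAC libraries yielded 69639 regions in control, 70942 in WIN, 76590 in cocaine and 76884 in WIN with cocaine. The regions of the 2 cocaine-treated libraries were somewhat narrower, with median widths of 337 bp in cocaine and 343 bp in WIN with cocaine against 356 bp in control and 358 bp in WIN. Covered length was close in all libraries, at 27804221, 28563834, 28430928 and 29035933 bp in the order control, WIN, cocaine, WIN with cocaine. Median summit scores were 37, 37, 39 and 39 in that order, each on the authors' scale. No treatment has a second ATAC library, and these differences were not tested.

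Many accessible regions were shared by the 4 libraries. Of the control regions, 71.6% (95% Wilson interval 71.3% to 72.0%) overlapped a region in each of the other 3 libraries. Of 99896 active regions, 49737 held a region from all 4 libraries, 4366 from control alone, 4795 from WIN alone, 6189 from cocaine alone and 6747 from WIN with cocaine alone. With the 69639 highest-scoring regions of each library these were 5693 from control alone, 5451 from WIN alone, 4692 from cocaine alone and 5034 from WIN with cocaine alone. This cut keeps every control region and drops the weakest regions of the larger libraries, and regions of a single library were mostly weak. The reversed order thus follows at least in part from the cut, and neither order shows an effect of treatment. Regions called in both cocaine-treated libraries and neither other numbered 4054, and those in control and WIN alone 1855; with equal numbers these were 2761 and 2884. By covered bases the closest pair was cocaine and WIN with cocaine, with a Jaccard index of 0.648, followed by control and WIN at 0.625; the other 4 pairs ran from 0.608 to 0.615.

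**Figure D4:**
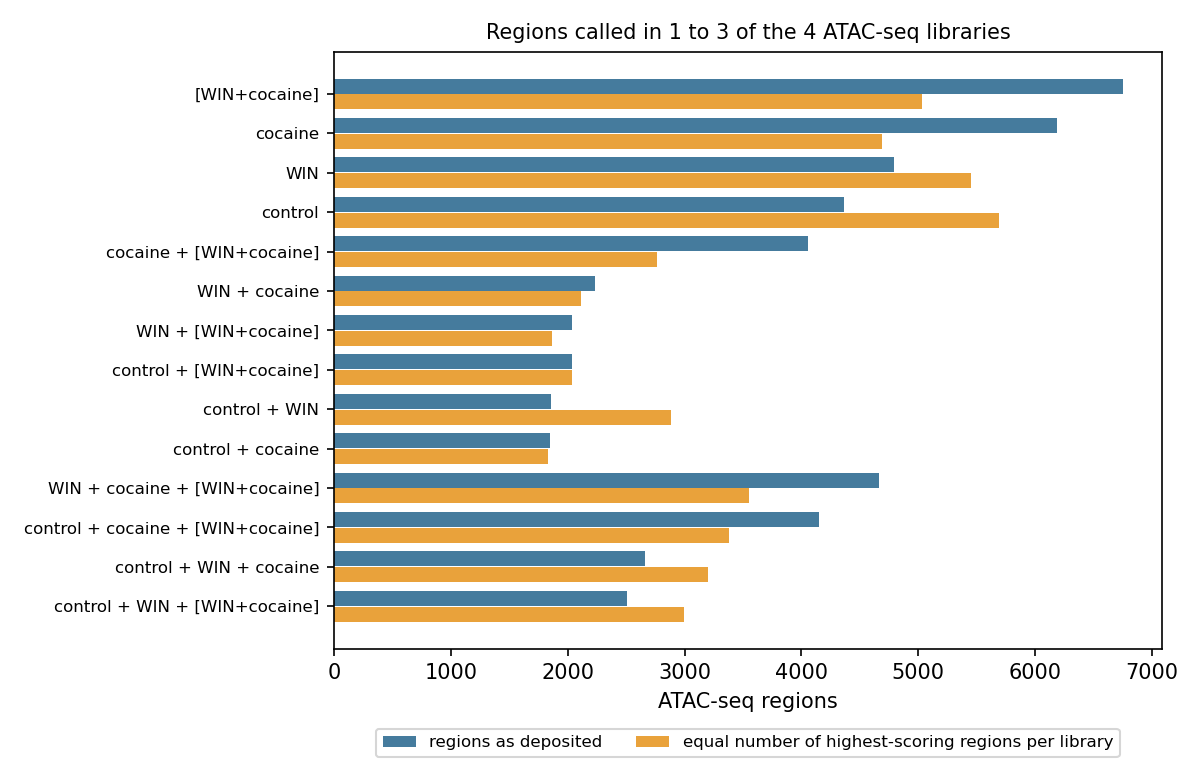
Number of active regions (horizontal axis) by the libraries in which they were called, for regions found in 1 to 3 of the 4 ATAC libraries, as deposited (blue) and with the 69639 highest-scoring regions of each library (orange). The cocaine pair alone holds 4054 regions as deposited and 2761 with equal numbers.

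The highest-scoring regions found in 1 library alone are given at the positions in the deposited tracks, whose build is not given in the sources used here and which were not annotated with genes here. In control they lay on chromosome 18 at 37041418 to 37041754 with a summit score of 131, on chromosome 16 at 58844749 to 58845106 with 106, and on chromosome 11 at 22351806 to 22352149 with 89. In WIN they lay on chromosome 20 at 56192112 to 56192311 with 151, on chromosome 1 at 55704808 to 55705312 with 128, and on chromosome 14 at 46648978 to 46649258 with 105. In cocaine they lay on chromosome 13 at 90695756 to 90696038 with 97, on chromosome 9 at 10990052 to 10990251 with 90, and on chromosome 3 at 2446102 to 2446375 with 88. In WIN with cocaine they lay on chromosome 2 at 197757436 to 197757733 with 88, on chromosome 4 at 68593811 to 68594092 with 84, and on chromosome 1 at 273854192 to 273854489 with 78. Regions of 1 library alone were mostly weak, with median scores of 23 in control and WIN and 24 in the other 2 libraries.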

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

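The fits with voom, the fits without a library of the groups not compared, and the alternatives of the score were chosen after the data were examined. For cocaine against control, limma called 0 genes in 16 of 24 alternatives. It called 2083 with library weights, 2276 with voom and quality weights, 1378 with only the libraries compared and 3037 at a threshold of 0.10; leaving out replicates gave 0 to 2772, with 1 gene without control replicate 1, 1 without control replicate 2 and 2772 without WIN replicate 3. Library weights gave WIN replicate 3 a weight of 0.30, the lowest of the 12; apart from that, the cause was not tested. The 4 IDs kept their direction in all 23 alternatives each, with adjusted p from 0.00758 to 0.24. They were chosen for their p in this comparison and the alternatives reuse most of the same libraries, so the kept direction adds no support. The other comparisons stayed at 0 in nearly all alternatives. WIN with cocaine against cocaine gave 1 gene with only the libraries compared and 0 to 1 over the left-out replicates (1 without WIN replicate 3 and 1 without control replicate 3). WIN against control, WIN with cocaine against control and the interaction each gave 0 to 1, with 1 gene without control replicate 2, and for the interaction also 1 without control replicate 1; the cause was not tested. WIN with cocaine against WIN stayed at 0 in all 24, and its count at an unadjusted p under 0.05 ran from 359 without WIN replicate 2 to 2261 without WIN replicate 3.

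With the replicate number as a block, 3 genes were called in cocaine against control and 0 in the other 5 comparisons. Expression gave little sign of pairing by number. Deviations of same-numbered libraries correlated from -0.281 to 0.196 with a median of 0.014, beside a median of -0.016 for other numbers. Of the 12 libraries, 4 were closest to a library of their own number. These values cannot show whether the numbers mark a batch or an animal.

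The correlation of the WIN changes ran from -0.344 to 0.005 over the left-out libraries, changing sign without WIN replicate 3, and that of the cocaine changes from 0.007 without WIN replicate 1 to 0.395 without WIN replicate 3. The score difference between WIN with cocaine and WIN, 0.22, ran from 0.06 to 0.48 over the same libraries. Taking the higher-scoring 50% of each ATAC library leaves by construction 34819, 35471, 38295 and 38442 regions in control, WIN, cocaine and WIN with cocaine; the share of control regions found in the other 3 libraries was then 72.4%, and 66.6% with a reciprocal overlap of 50%. The alternatives of the gene lists and of the promoter shares were not run, because the IDs could not be matched to symbols.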

Other observations

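All tests in this part were chosen after the group differences were seen; for all but the counts over 10 splits, what each outcome would mean was written before its result. The difference between cocaine and control libraries was spread over many genes. A trend with gene length and unequal depth are argued against as its whole cause, since 4876 genes had an unadjusted p under 0.05 after each library's length trend was removed and 4685 after all libraries were thinned to 20852442 reads, beside 4768 before. The 10 splits of the 6 libraries are too few for a share under 0.05; the real value was 4768 and the highest other split gave 921, and 1 of the 10 splits, the real one, gave as many. A batch shared by the cocaine libraries and a difference in dissection stay open, and cocaine itself remains a hypothesis.

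A second pattern is a smaller cocaine response after WIN in the genes that separated cocaine from control. Genes were chosen on 2 cocaine and 2 control libraries and measured in the left-out pair. Over the 9 pairs the held-out cocaine change in the score was 0.63 (SD 0.16, from 0.405 to 0.897). In the same genes WIN with cocaine minus WIN was 0.18 (from 0.128 to 0.225), so a gap of 0.45 remained in libraries not used to choose the genes. The genes were still chosen on cocaine against control, so a response of equal size in partly other genes would also score lower. The gap therefore covers these genes only. The pairs reuse 3 cocaine and 3 control libraries, and their SD holds no spread of the WIN or WIN+cocaine libraries. It therefore does not measure how certain the gap is. Without WIN replicate 3 the gap was 0.29, between 1 and 2 of these SD. The part that rests on the WIN group, WIN minus held-out control, was 0.13 (-0.003 to 0.352 over the pairs). It was 0.277 to 0.352 with control replicate 2 held out and at most 0.058 with another control held out. For this part, the position of WIN replicate 3, that of control replicate 2 and a smaller response cannot be told apart. The larger part, held-out cocaine minus WIN with cocaine, was 0.32 (0.18 to 0.42 over the pairs) and uses no score of the WIN group. With 3 libraries per group neither part was tested. A batch shared by the cocaine libraries, left open above, could also enter the larger part, and a biological effect of WIN stays open too. The test of the difference itself does not exclude chance: 16 of 100 exchanges of the WIN label gave at least the 1382 genes of the real interaction, and the highest of the others gave 3615.

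The remaining comparisons have 10 splits each, too few for a share under 0.05. WIN with cocaine against cocaine gave 1623 genes at an unadjusted p under 0.05 and at most 1288 in another split, and WIN with cocaine against control gave 1212 and at most 989; in each, 1 of 10 splits, the real one, gave as many. For WIN against control, 8 of 10 splits gave at least the real 238, with 1674 at most, and for WIN with cocaine against WIN, 7 of 10 gave at least the real 576, with 3170 at most. The splits with 1674 and 3170 genes both part WIN replicate 3 from WIN replicates 1 and 2, which points to a structure of the samples that the groups do not follow. WIN replicate 3 had a cocaine score of 0.32, beside -0.32 and -0.16 in the other WIN libraries and 0.35, 0.07 and 0.09 in WIN with cocaine; whether it is a mislabelled library, another dissection or an animal that differed was not tested.

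The third pattern is the excess of ATAC regions called in both cocaine-treated libraries and neither other, 4054 beside 1855 in control and WIN alone. With the 69639 highest-scoring regions of each library the ratio of these counts was 0.957 where it had been 2.19, so the excess goes with the number of regions called. Taking equal numbers would also remove a real gain of open regions in the cocaine-treated libraries. The ratio therefore cannot tell such a gain from more regions being called for another reason. With equal numbers both pairs, at 2761 and 2884 regions, still exceeded the 4 crossed pairs, which held 1835 to 2112. A candidate explanation is a chromatin difference that follows cocaine. Handling in pairs cannot be told apart from it, because each treatment has 1 library and the track names of the cocaine-treated pair follow another form than those of the other pair.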
